A study of Mus musculus with 12 samples.

How the data were processed

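MC3T3-E1 is a mouse preosteoblast line from skull bone that forms a mineralizing matrix in culture. Per the labels' protocols, cells were plated in medium with a glycerol phosphate and ascorbic acid, the medium was changed at intervals, and total RNA was taken on Day 2, Day 5, Day 10 or Day 28. Per the labels, each array carried cDNA of the cells in Cy3 and cDNA of a commercial mouse reference RNA in Cy5, on slides printed with a set of long oligonucleotides for mouse genes. There were 12 arrays, 3 for each day, and the dyes were not exchanged on any of them. The labels number the replicates of each day 1 to 3 and do not say whether they came from separate cultures, so p-values measure the spread between these arrays, which can be technical in part.

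The values are log ratios of cells and reference as deposited by the authors, 1 column per array, and were taken as log2. The submitters' processing notes name R version 2.13.0. Background correction, normalization within arrays, treatment of weak spots, the base of the logarithm and the direction of the ratio are not given in the sources used here. The column medians lay within 0.0132 of 0, so the columns came close to centred, and none of the 17664 rows had a missing value. No spot intensities were used, so weak spots could not be told from bright ones, and a large ratio of a weakly expressed gene carries that limit. For arrays, precision is limited by their number, here 3 for each day.

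The direction of the ratio was settled with gene lists chosen before the data were examined. On average over the 12 arrays, 18 genes typical of mesenchymal cells had a mean log2 ratio of 1.69 (SD 1.60, 16 above 0), and 24 genes of other lineages had a mean of -1.25 (SD 1.91, 10 above 0). The difference of 2.94 had a two-sided permutation p = 1e-05 across genes, the smallest that 100000 resamples can give. Positive values were therefore read as higher in the cells than in the reference, which is likely and not stated by the labels. Were the ratio the other way round, every direction given here would turn.

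Rows were named from the platform's probe annotation, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene spans only. Of the rows, 14010 had 1 gene, 13 had several and 3641 had none, and 13908 of those with 1 gene matched the table. Together they named 12817 genes. Rows with no gene stayed in the fit, because control spots could not be told from unnamed genes among them. For 10 genes printed 17 times each, the 170 spots were averaged to 1 row per gene, which left 17504 rows. A total of 963 genes had more than 1 probe, and these were tested separately. In the list tests a gene was represented by its probe with the lowest number. Among genes with several probes and at least 1 past the threshold, probes differed in sign for 3 of 9 genes in Day 5 against Day 2, 1 of 6 in Day 10 against Day 5, 1 of 13 in Day 28 against Day 10, and 25 of 99 in Day 28 against Day 2.

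Each array was centred on its median. A linear model with 1 mean per day was fitted to all 12 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes), which left 8 residual and gave 5.23 prior degrees of freedom. The comparisons were Day 5 with Day 2, Day 10 with Day 5, Day 28 with Day 10, and Day 28 with Day 2, along with an F test of any change over the 4 days. P-values were adjusted by the Benjamini-Hochberg method over all rows, and 0.05 was the threshold. A rise or fall is a difference past it. Log2 differences are the later day minus the earlier, with the standard error (SE) of the fit, and SDs are over the 3 arrays of a day.

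The 24 gene lists, fixed before the data were examined, covered osteoblast differentiation and mineralization, collagens and collagen modification, non-collagen matrix proteins, DNA replication, mitosis, cell cycle inhibitors and growth arrest, cholesterol synthesis, adipocyte, chondrocyte, skeletal muscle, and macrophage and osteoclast markers, smooth muscle contractile genes, interferon response, the Wnt pathway, the BMP and TGF-beta pathway, the insulin-like growth factor axis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, endoplasmic reticulum chaperones and secretion, matrix proteases and inhibitors, immediate early and stress genes, complement and acute phase, and cytokines and chemokines. Each was tested with camera from limma against all other rows, with a preset correlation of 0.01 between genes, and adjusted over the 24 lists within a comparison. The tests were repeated with an estimated correlation and with fry. With fry, all calls of mitosis, DNA replication and glycolysis were lost. So were those of collagens and matrix proteases in Day 10 against Day 5. Macrophage markers and oxidative phosphorylation lost theirs in Day 28 against Day 10. Cholesterol synthesis lost its calls in both of these comparisons and kept that of Day 28 against Day 2. With the estimated correlation the calls that held were those of the ribosomal proteins in Day 28 against Day 10, and of collagens, non-collagen matrix proteins, the insulin-like growth factor axis, ribosomal proteins, and matrix proteases in Day 28 against Day 2.

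Genes were named by a rule set before the data were examined. In each comparison it took up to 10 rises and 10 falls with the largest change among probes past the threshold that had 1 gene and no overlap between the arrays of the days compared, the 4 members of each list with the smallest p, and a few markers chosen beforehand. Genes named outside the rule are marked as such. Of the markers chosen beforehand, Sp7, Alpl, Ibsp, Col1a1, Col1a2, Mki67, Pcna and Cdkn1a were measured, and the others are not analysed here.

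The procedure was tested on simulated data built for Day 28 against Day 2 over 17504 rows, with 200 rows changed in each of 5 sets. It recovered 8.06% of changes of 0.5 on the log2 scale, 69.9% of changes of 1 and 97.0% of changes of 2, with 5.68% false calls among all calls. A list shifted by 0.3 was called in 5 of 5 sets and no other list was. The simulated noise was drawn independently for each gene, so these sets did not test list calls under correlation between genes. In the data the shifted list, mitosis, had an estimated correlation of 0.461. Changes of 0.5 were therefore mostly missed in the simulated sets. In the data 996 rows passed in Day 28 against Day 2, with differences down to 0.434 and 385 of them at 1 or more. The simulated shares therefore need not apply to the data. The alternatives tried were values without centring, quantile normalization, equal spread of all arrays, the replicate number as a block, a variance trend with robust fitting, array weights, probes averaged by gene, fits to only the 6 arrays compared, stricter thresholds, the other list tests, and each array left out in turn. Requiring complete rows, or dropping the filter on missing values, changed nothing since no value was missing.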

Results

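RNA of MC3T3-E1 cells was profiled at 4 stages of osteoblastic differentiation, with 3 arrays per day, each against the same reference RNA. The submitters take Day 2 as dividing preosteoblasts, Day 5 as cells that had stopped growing, Day 10 as cells in differentiation, and Day 28 as the mature stage. The series asked how gene expression changes from stage to stage. Values are log2 ratios to the reference on 17504 probes and averaged spots.

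The first principal component, with 28.1% of the variance, placed the days in order, from Day 2 (scores -25.6 to -21.9) to Day 28 (27.2 to 32.1). The second, with 16.7%, set apart Day 10 replicate 3 (42.3) and, less far, Day 5 replicate 2 (18.7). Their mean correlations with the other arrays of their day were 0.795 and 0.838, against 0.856 to 0.919 for the other 10 arrays. The median SD within a day was 0.178 on Day 2, 0.198 on Day 5, 0.189 on Day 10 and 0.138 on Day 28.

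**Figure D1:**
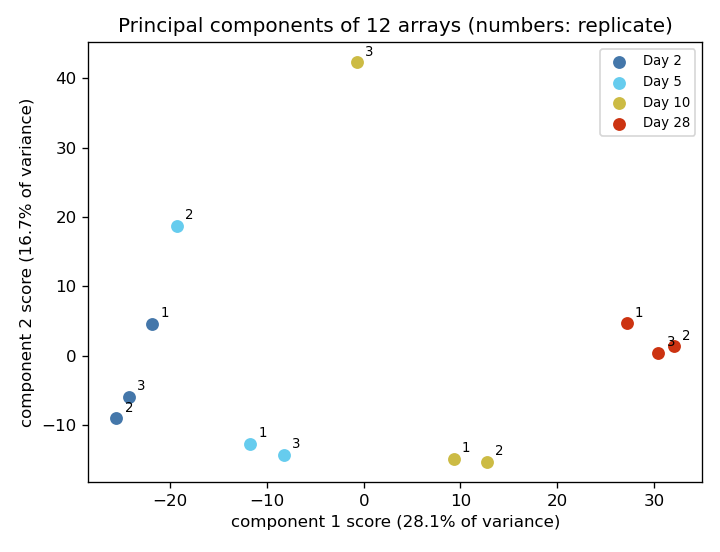
Scores of the 12 arrays on the first and second principal components of the centred log2 ratios, with the share of variance on each axis, coloured by day and numbered by replicate. The days follow each other along component 1, and Day 10 replicate 3 (42.3) and Day 5 replicate 2 (18.7) have the highest scores on component 2.

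Among the genes named here, F13a1 and Mmp13 rose most from Day 2 to Day 28. F13a1, which encodes the A subunit of the transglutaminase factor XIII, had a mean log2 ratio of -0.27 ± 0.22 on Day 2, 1.00 ± 0.44 on Day 5, 4.71 ± 1.11 on Day 10 and 8.54 ± 0.27 on Day 28 (SD, n = 3). Mmp13, collagenase 3, went from 0.81 ± 0.41 on Day 2 to 8.00 ± 0.10 on Day 28. The F test found a change over the 4 days for 931 of 17504 probes (5.32%), with 3274 at an unadjusted p under 0.05. Of these 931, 482 had their highest mean on Day 28, 211 on Day 2, 155 on Day 5 and 83 on Day 10. The lowest mean was on Day 2 for 401, Day 28 for 247, Day 5 for 182 and Day 10 for 101. With Day 5 replicate 2 and Day 10 replicate 3 left out, an alternative chosen after seeing the data, the F test called 1764 probes, with 715, 469, 306 and 274 highest on Day 28, Day 2, Day 5 and Day 10 and 487, 690, 303 and 284 lowest. The count was also 612 and 596 without Day 2 replicates 2 and 3, 1429 without Day 10 replicate 3, and 528, 520 and 515 without Day 28 replicates 1, 2 and 3.

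**Figure D2:**
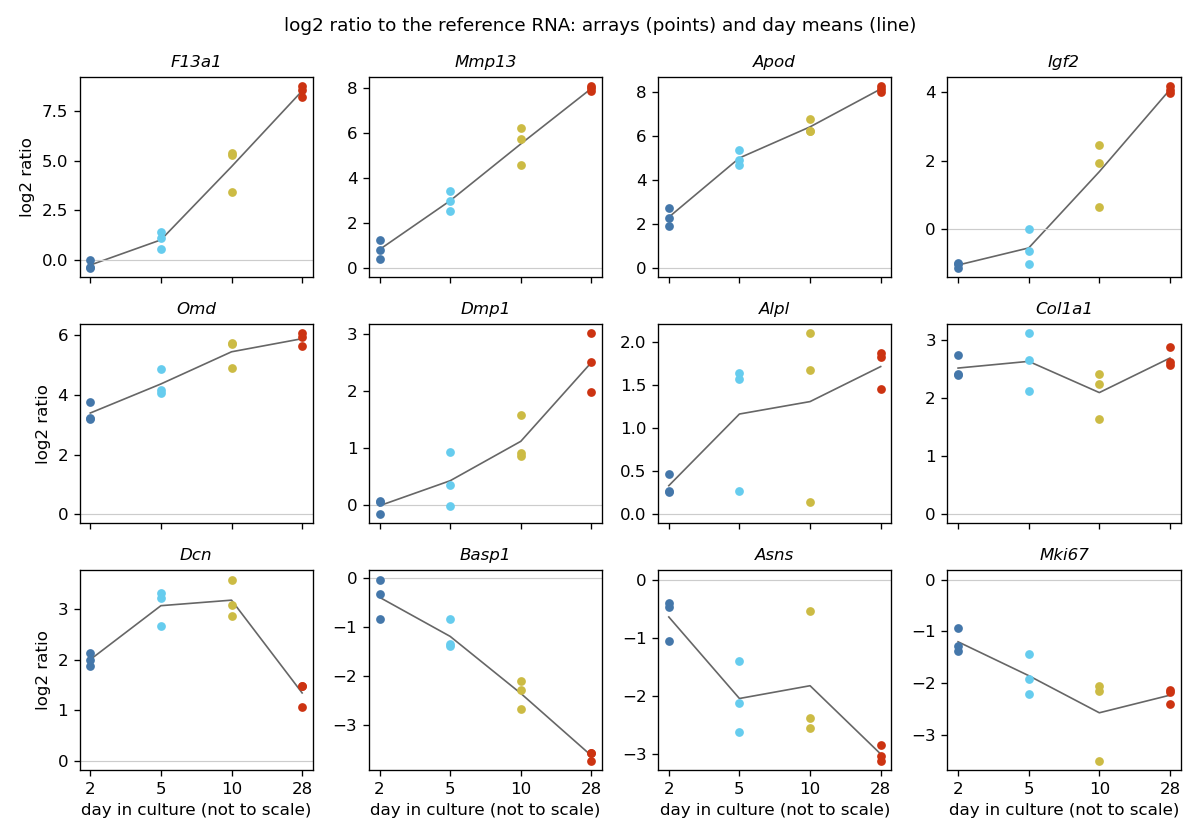
Log2 ratio to the reference RNA on each array (points, 3 per day) and the mean of each day (line) for 12 named genes, against the day in culture with days evenly spaced. F13a1 rose from -0.27 on Day 2 to 8.54 on Day 28 and Basp1 fell from -0.39 to -3.64, while the means of Col1a1 stayed between 2.10 and 2.69.

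Day 5 was compared with Day 2 to follow cells from division to growth arrest. Apod, a secreted lipocalin, led the rises at 6.48-fold (log2 difference 2.70, SE 0.23, limma adjusted p = 3.99e-04). Other rises were Tnfrsf19, a receptor of the tumour necrosis factor family (2.27), Mmp13 (2.18), Megf10 (2.15), Agt, which encodes angiotensinogen (2.02), Tnnc1, a troponin (1.75), and Col24a1, a fibrillar collagen (1.68). The largest fall was that of Id3, an inhibitor of basic helix-loop-helix factors and a target of BMP signalling, by 2.26 (SE 0.34, adjusted p = 0.013). Slpi, a protease inhibitor, fell by 1.75, Ly6c1 by 1.64, Olfr155 by 1.54, and the transcription factor gene Cebpd by 1.30, while Cebpa, of the same family, rose by 1.26. In all, 59 probes passed, 35 higher and 24 lower, and 1773 had an unadjusted p under 0.05. After quantile normalization the split was 38 higher and 40 lower.

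Cell division genes were lower as a group on Day 5. Of 42 measured mitosis genes, 41 were below their Day 2 level and the median difference was -0.58 (adjusted p = 2.45e-13 by camera, adjusted p = 0.475 with an estimated correlation). No single member passed, over all probes or adjusted over the list alone. Cenpf, a kinetochore protein, differed by -1.43 (adjusted p = 0.29) and Mki67, a proliferation marker, by -0.65 (adjusted p = 0.515). The DNA replication list had a median of -0.26 over 43 genes, none of them past the threshold (adjusted p = 1.13e-05, adjusted p = 0.492 with an estimated correlation), and its call was lost without Day 5 replicate 1 (median -0.09). That array had the lowest mitosis and DNA replication medians of its day, at -0.33 and -0.34. Endoplasmic reticulum chaperones had a median of -0.21, with 0 of 24 members past the threshold in limma (adjusted p = 5.24e-04, adjusted p = 0.0618 with an estimated correlation). Glycolysis had a median of -0.35 over 15 genes (adjusted p = 0.00699, adjusted p = 0.492 with an estimated correlation), a call lost without Day 2 replicate 1 (median -0.15), without Day 5 replicate 1, after quantile normalization and with equal spread.

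Other lists had single members past the threshold and were not called. Both Id1 (-1.25) and Id3 fell among 33 genes of the BMP and TGF-beta pathway, and adjusted over the list alone 2 rose and 5 fell. Of 24 cell cycle inhibitors and growth arrest genes 1 rose, Gas6, by 1.43, and 1 fell, Gadd45b, by 0.70 (1 and 2 adjusted over the list alone). Of 32 non-collagen matrix genes 1 rose, Postn, which encodes periostin, by 1.29, and 1 fell, Ltbp2, by 1.10 (6 and 4 adjusted over the list alone). The calls of Gas6, Postn and Ltbp2 were lost after quantile normalization and with equal spread of the arrays. Of the 21 osteoblast genes 1 rose and none fell (adjusted p = 0.0847), and adjusted over the list alone 2 rose and 1 fell. The alkaline phosphatase gene Alpl went from 0.33 ± 0.11 to 1.17 ± 0.77 (difference 0.83, adjusted p = 0.544). The cell cycle inhibitor Cdkn1a differed by 0.60 (adjusted p = 0.596).

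The count in Day 5 against Day 2 depended on the arrays used. It was 231 without both arrays that stood apart, 160 without Day 10 replicate 3 alone, 28, 21 and 22 without Day 2 replicates 1, 2 and 3, 24 and 20 without Day 5 replicates 1 and 3, 36 and 33 without Day 28 replicates 1 and 2, and 37 from the 6 arrays compared. Of 25 genes that the naming rule took and that passed, 10 stayed past the threshold whichever array was left out, among them Apod, Tnfrsf19, Agt, Tnnc1, Col24a1, Ly6c1, Olfr155 and Cebpd, while Mmp13, Megf10, Id3, Id1, Slpi, Postn and Cebpa each lost their call without at least 1 array.

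Day 10 was compared with Day 5 to follow growth-arrested cells into differentiation. F13a1 rose 13.0-fold (3.70, SE 0.41, adjusted p = 0.00416), and Mmp13 rose again by 2.53. Further rises were those of Igf2, an insulin-like growth factor (2.22), Cd200, a membrane glycoprotein (1.84), Mfap5, a protein of elastic microfibrils (1.73, adjusted p = 6.2e-04), Agt (1.62), Apod (1.42), Tns1, which links integrins to actin (1.26), Fxyd1 (1.26) and Chrdl1, a BMP antagonist (1.26). Tnnc1, which had risen on Day 5, fell by 1.40, and Rtp4, Dpysl2 and the interferon-induced Isg15 fell by 1.19, 0.97 and 0.95. After quantile normalization Apod, Tns1, Dpysl2 and Isg15 lost their calls. With probes of a gene averaged, Cd200, Tns1 and Chrdl1 lost theirs. In all 26 probes passed, 21 higher and 5 lower, and 1573 had an unadjusted p under 0.05.

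Cholesterol synthesis was the list with the smallest p. Its 17 measured genes had a median difference of -0.46, with 1 member above 0 (adjusted p = 1.01e-07, adjusted p = 0.191 with an estimated correlation). None passed over all probes and 4 fell adjusted over the list alone. The Day 10 medians were -0.02, 0.11 and -0.39 on replicates 1, 2 and 3, and without replicate 3 the difference was -0.26 and the call held. Dhcr7 differed by -0.83 (adjusted p = 0.109) and Fdps by -0.71 (adjusted p = 0.118). Complement and acute phase genes were higher, with a median of 0.21 over 10 genes and 3 rises adjusted over the list alone (adjusted p = 0.00636, adjusted p = 0.191 with an estimated correlation). Collagens had a median of 0.11 over 34 genes, none past over all probes and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00636, adjusted p = 0.218 with an estimated correlation), a call lost after quantile normalization, and the median was 0.06, 0.04 and 0.21 without Day 10 replicates 1, 2 and 3. Col15a1 differed by 2.42 (adjusted p = 0.0685). In the insulin-like growth factor axis 1 of 14 genes rose, Igf2, and 3 adjusted over the list alone. Its median of 0.05 became -0.05 after quantile normalization, where the call was lost (adjusted p = 0.0252, adjusted p = 0.191 with an estimated correlation), and was 0.20 and -0.0072 without Day 5 replicates 1 and 3 and -0.05 and 0.35 without Day 10 replicates 1 and 3. Matrix proteases had 1 rise among 22 genes, Mmp13, and 3 adjusted over the list alone, with a median of 0.08 (adjusted p = 0.044, adjusted p = 0.348 with an estimated correlation), which was 0.05 without Day 5 replicate 1 and 0.13 without Day 10 replicate 1. This call was also lost with equal spread, the replicate block, array weights, rows with 1 gene only, and without both arrays that stood apart. With fry it was lost too, as were those of collagens, cholesterol synthesis, mitosis and DNA replication.

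The lower values of cell division genes on Day 10 rested on replicate 3 of that day. Mitosis had a median difference of -0.29 (adjusted p = 7.88e-04, adjusted p = 0.588 with an estimated correlation) and DNA replication of -0.15 (adjusted p = 0.0252, adjusted p = 0.643 with an estimated correlation), and none of their members passed. The mitosis median was -1.03 on Day 10 replicate 3 and -0.03 and 0.03 on replicates 1 and 2. Without replicate 3 the medians turned to 0.05 and 0.07 and neither passed. Both calls were also lost without Day 5 replicate 3, and that of DNA replication without Day 5 replicate 2 (median -0.05). The mitosis median was -0.17 without Day 5 replicate 3, -0.50 without Day 5 replicate 1, and -0.52 and -0.53 without Day 10 replicates 1 and 2, and that of DNA replication -0.28 without Day 5 replicate 1.

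**Figure D3:**
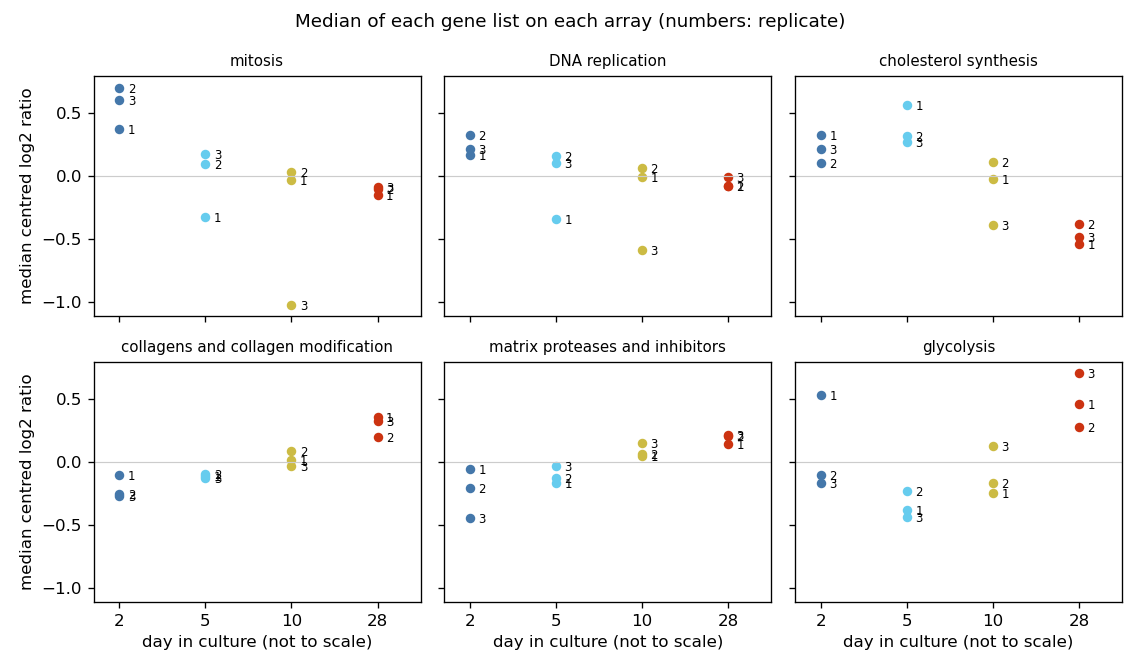
Median over the genes of 6 lists of the log2 ratio, each gene centred on its mean over the 12 arrays, for each array (points, numbered by replicate) against the day in culture with days evenly spaced. For mitosis, Day 10 replicate 3 lies at -1.03 while Day 10 replicates 1 and 2 lie at -0.03 and 0.03, and for glycolysis Day 2 replicate 1 lies at 0.53.

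Few calls between Day 5 and Day 10 were stable. With limma on the 6 arrays alone 0 probes passed (1101 at an unadjusted p under 0.05), and the count was 52 without both arrays that stood apart, 83 without Day 10 replicate 3, 4 and 4 without Day 10 replicates 1 and 2, 1, 11 and 17 without Day 5 replicates 1, 2 and 3, 14 and 16 without Day 2 replicates 2 and 3, and 12 without any 1 of the Day 28 arrays. Among 14 named genes that passed, Mfap5 alone kept its call without each array. F13a1 lost its call without Day 5 replicate 1 and kept it without each of the other arrays. Of the 7 list calls 1 held without each array, that of cholesterol synthesis. Collagens lost theirs without Day 5 replicate 3, complement without Day 10 replicate 3, the insulin-like growth factor axis without Day 5 replicate 2 or 3 or Day 10 replicate 1, and matrix proteases without any 1 of 7 arrays.

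Day 28 was compared with Day 10 to follow differentiating cells to maturity. The rise of F13a1 went on, 14.2-fold (3.83, SE 0.41, adjusted p = 5.63e-04). The chemokine gene Ccl8 rose 10.3-fold (3.37, SE 0.20, adjusted p = 3.5e-06), Clec3b, which encodes the plasminogen-binding tetranectin, by 3.36, Dio2, which activates thyroid hormone, by 3.29, and Ighm, an immunoglobulin heavy chain gene, by 3.25. Fbln7, a fibulin, rose by 3.17, Cd200 by 2.96, Mmp13 by 2.48, Car9, a carbonic anhydrase, by 2.47 and Igf2 by 2.39. The tight junction gene Cldn1 fell by 2.36 and Dcn, the matrix proteoglycan decorin, by 1.83 (SE 0.21, adjusted p = 0.00106). Basp1 fell by 1.28, Ralgps2 by 1.14, Kif21a by 1.06, Bcat1, which transfers amino groups of branched-chain amino acids, by 1.03, and Sox11 by 1.00. The calls of Ralgps2 and Sox11 were lost with probes of a gene averaged. In all 147 probes passed, 124 higher and 23 lower (67 and 23 after quantile normalization, 287 and 133 with array weights), and 1884 had an unadjusted p under 0.05.

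Matrix genes were higher as groups. Of 34 collagen genes 2 rose, Col18a1 (1.62) and Plod1, a lysyl hydroxylase (0.95), and 8 adjusted over the list alone, with a median of 0.30 (adjusted p = 3.65e-06, adjusted p = 0.0736 with an estimated correlation). Non-collagen matrix proteins had 2 rises, Matn2 (0.96) and Ltbp2 (1.04), and 1 fall, Dcn, among 32, with 6 rises and 1 fall adjusted over the list alone and a median of 0.18 (adjusted p = 0.00577, adjusted p = 0.0765 with an estimated correlation). The median was 0.28 without Day 10 replicate 2, and the call was lost without Day 10 replicate 3 (median 0.11) and after quantile normalization. Matrix proteases and inhibitors had 4 rises among 22, Mmp13, Timp1 (0.93), Ctsl (1.00) and Htra1 (0.95), and 6 adjusted over the list alone (median 0.19, adjusted p = 0.00133, adjusted p = 0.108 with an estimated correlation). After quantile normalization Plod1, Matn2, Ltbp2, Timp1, Ctsl and Htra1 lost their calls, and Col18a1, Dcn and Mmp13 kept theirs. Plod1 also lost its call with probes of a gene averaged. Among osteoblast genes Dmp1, a mineralization protein of osteocytes, rose by 1.39 and Tnfrsf11b, which encodes osteoprotegerin, by 1.09, 2 of 21 (adjusted p = 0.187 for the list), and adjusted over the list alone 2 rose and 2 fell. Both lost their call after quantile normalization. Of 28 Wnt pathway genes Sfrp2 and Ccn5 rose, over all probes and adjusted over the list alone (adjusted p = 0.339 for the list), and both calls were lost after quantile normalization.

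Of 14 genes of the insulin-like growth factor axis, Igf2 and Igfbp5 (2.01) rose, 3 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.00658, adjusted p = 0.0736 with an estimated correlation), or 0.15 without Day 10 replicate 3, and the call was lost with probes of a gene averaged. In the BMP and TGF-beta pathway Grem1, a BMP antagonist (1.79), and Tgfb1 (1.42) rose, 2 of 33 and 5 adjusted over the list alone (median 0.19, adjusted p = 0.00166, adjusted p = 0.0736 with an estimated correlation). The cytokine Il33 rose by 1.98 and Cnmd, a chondrocyte marker that encodes chondromodulin, by 1.40.

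All 15 glycolysis genes were higher on Day 28, with a median of 0.50, none past the threshold over all probes and 7 adjusted over the list alone (adjusted p = 3.19e-06, adjusted p = 0.14 with an estimated correlation). Pgk1 differed by 1.61 (adjusted p = 0.0542). Oxidative phosphorylation genes had a median of 0.14 with 38 of 50 above 0, none of them past over all probes and 1 lower adjusted over the list alone (adjusted p = 0.00155, adjusted p = 0.388 with an estimated correlation). Cytosolic ribosomal protein genes were lower with both correlations, with a median of -0.15 over 57 genes (adjusted p = 1.06e-08, adjusted p = 0.00127 with an estimated correlation). Of these, Rps7 (-1.10), Rpl37 (-1.08), Rpl14 (-1.02), Rpl8 (-0.97), Rps12 (-0.86) and Rps3a1 (-0.60) fell, 11 adjusted over the list alone. Rps7 kept its call without each array, while with 1 of the 12 arrays left out in turn Rpl37 and Rpl14 kept theirs 2 times and Rps3a1 0 times, and these last 3 also lost it after quantile normalization. Cholesterol synthesis had a median of -0.41 (adjusted p = 3.65e-06, adjusted p = 0.14 with an estimated correlation), with no member of 17 past over all probes, and 6 lower and 1 higher adjusted over the list alone.

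The calls of the interferon, macrophage and mitosis lists were less stable. Interferon response genes had 1 rise among 23, Ifi47 (1.20), over all probes and adjusted over the list alone, and a median of 0.18 (adjusted p = 0.0119, adjusted p = 0.14 with an estimated correlation), a call lost without Day 10 replicate 1 (median 0.07) or Day 28 replicate 1. The call of Ifi47 was lost after quantile normalization. Macrophage and osteoclast markers had a median of 0.19 with no member of 18 past, over all probes or adjusted over the list alone (adjusted p = 0.0366, adjusted p = 0.14 with an estimated correlation), and lost the call without Day 10 replicate 1 or 2, without Day 28 replicate 1, and after quantile normalization. Tyrobp and Fcer1g, abundant in macrophages and chosen after their values were seen, differed by -0.07 and 0.06, while 12 of the 18 markers were above 0. The mitosis list had a median of 0.21 (adjusted p = 0.0462, adjusted p = 0.71 with an estimated correlation) and no member past in either way. Without Day 10 replicate 3, whose mitosis median was -1.03, the median turned to -0.13, past the threshold in the other direction, and the call was also lost without Day 5 replicate 2 or 3 and Day 28 replicate 2 or 3. The median was 0.33 without Day 10 replicate 1 and without replicate 2.

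The count for Day 28 against Day 10 was 261 without both arrays that stood apart, 90 after quantile normalization, 65 from the 6 arrays compared, 79 without Day 10 replicate 1, and 65, 81 and 69 without Day 28 replicates 1, 2 and 3. Of 40 named genes that passed, 19 kept their call whichever array was left out, among them F13a1, Ccl8, Clec3b, Dio2, Ighm, Fbln7, Cd200, Mmp13, Car9, Igf2, Cldn1, Dcn, Rps7, Col18a1, Igfbp5, Grem1 and Il33.

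Day 28 was compared with Day 2 to set mature osteoblasts against dividing preosteoblasts. F13a1 was 448-fold higher (8.81, SE 0.41, adjusted p = 9.23e-08), Mmp13 145-fold (7.18, SE 0.34, adjusted p = 9.34e-08), Apod 57.2-fold (5.84) and Igf2 34.3-fold (5.10). Cd200 rose by 5.63, Col15a1, a collagen of basement membranes, by 4.90, Clec3b by 4.64, Ecrg4 by 4.26, Lum, the matrix proteoglycan lumican, by 4.12 and Dio2 by 4.10. The largest fall was that of Basp1, by 3.25 (SE 0.22, adjusted p = 1.78e-06), then Chac1, which degrades glutathione, by 2.72, Vstm5 by 2.52, Bcat1 by 2.46, Asns, asparagine synthetase, by 2.35, Crybg1 by 2.29, Pcolce2 by 2.28, the sulfotransferase gene Chst1 by 2.00, Slpi by 1.96 and Gja1, the gap junction protein connexin 43, by 1.83. In all 996 probes passed, 644 higher and 352 lower, of which 606 and 310 had 1 named gene, and 3196 had an unadjusted p under 0.05. The split was 559 higher and 445 lower after quantile normalization and 885 and 664 from the 6 arrays compared.

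Osteoblast and matrix genes were higher on Day 28. Of 21 osteoblast genes 5 rose and 1 fell, 8 and 2 adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0038, adjusted p = 0.0722 with an estimated correlation), and the call was lost after quantile normalization. The median was 0.32 and 0.10 without Day 2 replicates 1 and 3 and 0.27 without Day 28 replicate 2 or 3. Dmp1 rose by 2.52, Omd, the mineral-binding osteoadherin, by 2.48, Pth1r, the parathyroid hormone receptor, by 1.84, and Tnfrsf11b by 0.94, a call lost after quantile normalization. Outside the naming rule, chosen after their values were seen, Cdh11 rose by 0.51 and Atf4, a transcription factor of amino acid metabolism, fell by 0.79. Alpl differed by 1.39 (adjusted p = 0.0854), Ibsp, bone sialoprotein, by 1.56 (adjusted p = 0.255) and Sp7, the transcription factor osterix, by 0.80 (adjusted p = 0.376). The means of Col1a1 lay between 2.10 and 2.69 on the 4 days, and the differences of Col1a1 (0.17, adjusted p = 0.786) and Col1a2 (0.57, adjusted p = 0.207) did not pass and became -0.52 and -0.40 after quantile normalization.

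Collagens had 10 rises and no fall among 34 genes, 12 rises adjusted over the list alone, with a median of 0.41 (adjusted p = 4.41e-10, adjusted p = 0.0336 with an estimated correlation). Col15a1 led, and Col18a1 rose by 2.69, Col5a3 by 1.79 and Col4a2 by 1.64. Non-collagen matrix proteins had 10 rises and 2 falls among 32, 13 and 4 adjusted over the list alone (median 0.25, adjusted p = 2.99e-04, adjusted p = 0.0336 with an estimated correlation), with Lum, Mfap5 (2.19), Matn2 (1.10) and Ltbp3 (0.80) among the rises, and the calls of the list and of Matn2 were lost after quantile normalization. Without Day 2 replicate 1 the median was 0.39. Matrix proteases and inhibitors had 10 rises and 1 fall among 22, 11 and 1 adjusted over the list alone (median 0.58, adjusted p = 2.74e-06, adjusted p = 0.0336 with an estimated correlation), with Mmp13, Htra1 (2.58), Plat, tissue plasminogen activator (1.68), and Ctsl (1.18). In the insulin-like growth factor axis 5 of 14 rose and 1 fell, over all probes and adjusted over the list alone (median 0.57, adjusted p = 0.00108, adjusted p = 0.0336 with an estimated correlation). Igf2, Igfbp5 (2.84) and Igfbp6 (0.89) were among the rises, and the receptor gene Igf1r fell by 0.88.

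Division, sterol and ribosomal genes were lower. Mitosis had a median of -0.72, with 3 falls among 42, Cdc25c (-0.98), Cks1b (-0.87) and Kif2c (-0.84), and 21 adjusted over the list alone (adjusted p = 1.64e-10, adjusted p = 0.252 with an estimated correlation). Mki67 differed by -1.03 (adjusted p = 0.0816). DNA replication had a median of -0.25 and 2 falls among 43, Orc6 (-0.90) and Dut (-0.67), and 1 adjusted over the list alone (adjusted p = 1.15e-04, adjusted p = 0.501 with an estimated correlation), while Pcna differed by -0.09. In cholesterol synthesis 7 of 17 fell, 12 adjusted over the list alone, among them Msmo1 (-1.07), Dhcr7 (-1.06), Fdps (-1.02) and Nsdhl (-0.82), with a median of -0.68 (adjusted p = 4.41e-10, adjusted p = 0.0646 with an estimated correlation). Ribosomal proteins had 6 falls and 1 rise among 57, 10 and 1 adjusted over the list alone, with a median of -0.11 (adjusted p = 0.0105, adjusted p = 0.0356 with an estimated correlation), and the call was lost after quantile normalization. Endoplasmic reticulum chaperones and secretion had 2 falls, Asns and Pdia6 (-0.59), and 1 rise, Creb3l1 (0.63), among 24, 5 and 2 adjusted over the list alone (median -0.14, adjusted p = 0.0221, adjusted p = 0.0722 with an estimated correlation). Glycolysis had 3 rises among 15, Pgk1 (1.41), Pgam1 (0.91) and Tpi1 (0.63), 4 adjusted over the list alone, and a median of 0.32 (adjusted p = 0.00488, adjusted p = 0.48 with an estimated correlation). The last 2 list calls were lost without Day 2 replicate 3 (glycolysis median 0.173, and 0.165 without Day 28 replicate 3), those of Dut and Creb3l1 after quantile normalization, and Day 2 replicate 1 had a glycolysis median of 0.53 against -0.11 and -0.17 on the other arrays of its day.

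The other 13 lists were not called in Day 28 against Day 2. Those of signalling and response were complement and acute phase (adjusted p = 0.0572), immediate early and stress (0.072), cytokines and chemokines (0.204), interferon response (0.354), the BMP and TGF-beta pathway (0.354), the Wnt pathway (0.819), oxidative phosphorylation (0.999) and cell cycle inhibitors (0.919). Those of other cell types were chondrocyte (0.48), smooth muscle (0.571), skeletal muscle (0.6), macrophage and osteoclast (0.773) and adipocyte markers (0.919). The median and the test had opposite signs for cell cycle inhibitors (median -0.01), macrophage and osteoclast markers (-0.04), the Wnt pathway (-0.06), and cytokines and chemokines (-0.03), all with a test towards higher values. The adipocyte median was -0.14 and its mean 0.04, and the oxidative phosphorylation median was 0.01 and its mean -0.01. Over all probes, members rose and fell in several of these lists, 5 and 2 of 20 cytokines and chemokines, 4 and 1 of 23 interferon response genes, 3 and 1 of 33 BMP and TGF-beta pathway genes, 3 and 0 of 10 complement genes and 0 and 3 of 50 oxidative phosphorylation genes. Adjusted over each list alone these were 5 and 3, 6 and 2, 5 and 3, 4 and 0, and 0 and 3. In the other 8 lists 1 or 2 rose and 0 fell over all probes. The falls were those of Ndufa4 (-1.17), Atp5b (-0.93), Ndufb8 (-0.54), Isg15 (-0.76), Id1 (-0.93) and, chosen after their values were seen, Ptn (-1.20) and Cxcl12 (-0.64). Among the rises were the chemokine genes Ccl8 (3.20) and Ccl7 (2.05), the cytokine Il33 (3.49), the complement genes C1ra (1.74) and C1s1 (1.56), ceruloplasmin Cp (1.98), Tgfb1 (1.79), Hspa1b (1.58), Ifi47 (1.54) and the class I antigen genes H2-D1 (1.38) and B2m (0.97). Ctsk, a collagen-degrading protease best known from osteoclasts, rose by 2.63, and Cebpa, an adipocyte transcription factor, by 1.64, while Fabp4 and Pparg, also adipocyte genes and chosen after their values were seen, differed by -0.23 and -0.19. The Wnt antagonist Sfrp2 rose by 1.27, but differed by -0.09 after quantile normalization.

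The count for Day 28 against Day 2 was 1704 without both arrays that stood apart, 1549 from the 6 arrays compared, 576 and 591 without Day 2 replicates 2 and 3, and 600, 529 and 547 without Day 28 replicates 1, 2 and 3. Of 82 named genes that passed, 66 kept their call whichever array was left out, and Chac1, Dut, Kif2c, Pgk1, Tpi1, Pgam1, Pdia6, Creb3l1 and 8 others did not.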

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

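The alternatives without both arrays that stood apart, with probes of 1 gene only and with repeated spots not averaged were chosen after seeing the data, and the others before. Values without centring, complete rows, and no filter on missing values left each of 193 named gene results and 34 list results in direction and on its side of the threshold. Of the gene results, quantile normalization weakened 28 and turned 1 that had passed, equal spread weakened 15, the trend with robust fitting 19, averaging a gene's probes 7, and fits to the 6 arrays compared weakened 44 and strengthened 3. Of the lists, quantile normalization weakened 10, the estimated correlation 28 and fry 16.

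Counts are given in the order Day 5 against Day 2, Day 10 against Day 5, Day 28 against Day 10, Day 28 against Day 2, then the F test. The main counts of 59, 26, 147, 996 and 931 became 14, 2, 56, 472 and 405 at an adjusted p under 0.01, through the stricter threshold itself. With a log2 change of at least 1, those that moved were 35, 95 and 385 in Day 5 against Day 2, Day 28 against Day 10 and Day 28 against Day 2. From only the 6 arrays compared the 4 counts were 37, 0 by limma (1101 at an unadjusted p under 0.05), 65 and 1549. Quantile normalization gave 90 in Day 28 against Day 10, and averaging a gene's probes gave 17 in Day 10 against Day 5. Array weights gave 420 and 1702 in the comparisons of Day 28 with Day 10 and Day 2, and 1655 by the F test, with 410, 282, 209 and 754 highest and 617, 283, 242 and 513 lowest on Day 2, 5, 10 and 28. Without both arrays that stood apart the counts were 231, 52, 261, 1704 and 1764, with 469, 306 and 274 highest and 690, 303 and 284 lowest on Day 2, 5 and 10. Apart from the stricter limits, the cause was not tested.

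With each array left out in turn the counts ranged from 20 to 160, 1 to 83, 65 to 198, 529 to 1431 and 515 to 1429, and the probes highest on Day 2, 5, 10 and 28 from 108 to 359, 57 to 237, 40 to 205 and 291 to 628, and those lowest from 257 to 566, 95 to 246, 48 to 216 and 103 to 401. Lists past the threshold, 4, 7, 12 and 11, ranged from 3 to 6, 2 to 8, 10 to 13 and 9 to 13. They were 0, 0, 1 and 5 with the estimated correlation in camera (2, 5, 8 and 8 at an unadjusted p under 0.05), 1 and 3 with fry in the first comparisons, and 7 and 4 there, both with array weights and without both arrays that stood apart. The 3 with fry in Day 10 against Day 5 included ribosomal proteins, which the main test had not called.

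Sfrp2 in Day 28 against Day 2 went from 1.27 to -0.0897 after quantile normalization. Under the same setting differences that had not passed changed sign for Col1a1 and Col1a2 in Day 5 against Day 2 and Day 28 against Day 2 and for Sp7 and Alpl in Day 10 against Day 5, as did the median of the insulin-like growth factor axis there, whose call was lost. The mitosis median in Day 28 against Day 10 went from 0.21 to 0.014 with array weights, with its test the other way, and to -0.129 without both arrays that stood apart. With each array left out in turn it ranged from -0.129 (without Day 10 replicate 3) to 0.332. In Day 10 against Day 5 the DNA replication median went from -0.15 to 0.12 and the mitosis median from -0.29 to 0.16 without both arrays, and with each array left out in turn they ranged from -0.282 to 0.0696 and from -0.526 to 0.0543, highest without Day 10 replicate 3. Day 10 replicate 3 had the lowest mitosis median of the 12 arrays, -1.03, and leaving it out moves the mean of its day, while the cause of its low value was not tested.

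With the replicate number as a block the counts were 30 in Day 5 against Day 2 and 13 in Day 10 against Day 5, and 97 probes of the F test were highest and 138 lowest on Day 5. The block weakened 26 of the 193 gene results and 1 of the 34 lists. The labels do not say whether the numbers pair the arrays. Deviations from the day mean correlated at -0.271 to 0.205 over 18 pairs of arrays with the same number. Over 36 other pairs they correlated at -0.331 to 0.394. Both ends of that range came from pairs with Day 5 replicate 2, which stood apart. For 5 arrays the best match had their own number. With 3 arrays per day these values cannot exclude a batch shared by number. The block also leaves fewer degrees of freedom. Signal over background is not analysed here, so what it limits is left open.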

Other observations

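The tests of independent noise and of the spread between arrays of a day were chosen only after the result was seen, and so were the 3 patterns weighed and the oxygen-limitation and amino acid lists, whose members were listed before their own values were seen, except Lox, Vegfa and Nupr1. Stc2 is in both lists.

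Id3, a target of BMP signalling, had means of 0.42 on Day 2, -1.84 on Day 5, -2.14 on Day 10 and -0.67 on Day 28, so its lowest means were in the middle of the course, and the difference between Day 10 and Day 28 (1.46) was not called. Id1, of the same family, fell by 1.25 on Day 5 and by 0.93 between Day 2 and Day 28. With each of the 12 arrays left out in turn, these calls of Id1 held 2 and 6 times. Cholesterol synthesis genes had a median change of 0.13 to Day 5, which was not called (adjusted p = 0.273), then -0.46 to Day 10 and -0.41 to Day 28, calls that are lost with an estimated correlation (adjusted p = 0.191 and 0.14).

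Other splits of the arrays were counted for the probe counts of the 4 comparisons and the F test. For the comparisons of 2 days, the real split gave the most calls, 1 of 10 splits, and the highest other count was 0, 7, 0 and 0 for Day 5 against Day 2, Day 10 against Day 5, Day 28 against Day 10 and Day 28 against Day 2. With 10 splits the share is too coarse to pass the threshold. For the F test 1 of 100 splits gave as many calls, the real one with 931, and the highest other gave 162. That share is the smallest that 100 splits can give, so it argues against a random split without excluding it. Causes shared by the arrays of a day are not addressed by such splits.

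Day 5 replicate 2 and Day 10 replicate 3 deviated together from the other arrays of their days. The correlation of their deviations was 0.394 across probes, against 0.205 for the next highest pair. Day 10 replicate 3 correlated better with Day 5 replicate 2 (0.835) than with the other arrays of its day (0.80 and 0.79). Both arrays had been picked because they stood apart on component 2 of the same data, which favours a shared deviation. These values therefore cannot decide about independent noise. An exchange needs each array nearer to the other's day. Day 10 replicate 3 lay near the middle of the way from Day 5 to Day 10, at 0.459 (95% bootstrap interval 0.432 to 0.489). Day 5 replicate 2, at 0.267 (0.238 to 0.293), lay nearer to its own day, which argues against an exchange. The intervals resample probes with the arrays held fixed, so they leave out the spread between arrays. Weaker signal from genes of long genomic span needs span and deviation to go the same way in both arrays, and the rank correlation was 0.0217 for Day 10 replicate 3 and -0.0438 for Day 5 replicate 2 over 13748 genes (lowest other array of those days -0.0323), which argues against it as the shared cause. RNA quality, handling and culture conditions stay open as untested, and no biological explanation was tested.

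Glycolysis genes and Car9 were higher on Day 28 than on Day 10, and a candidate explanation is less oxygen on Day 28. Of 26 genes listed for oxygen limitation 23 were measured, with a median of 0.31 (camera p = 6.59e-08, p = 0.0321 with an estimated correlation), and Fam162a (1.10) and Higd1a (1.00) rose, but the list was lower on Day 5 than on Day 2 (median -0.14, p = 0.00503, p = 0.216 with an estimated correlation). For Day 28 against Day 2 the median was 0.30, with 4 rises and 1 fall (camera p = 6.82e-04, p = 0.142 with an estimated correlation). Lox had been seen before, and without it the median in Day 28 against Day 10 was 0.29. That of the 23 genes was there 0.19 after quantile normalization and 0.49 without both arrays that stood apart. After quantile normalization the glycolysis median was 0.34 (adjusted p = 4.07e-04), which argues against scaling as the whole cause. Spread between arrays of a day could not be told apart from a change between days, since the glycolysis p with an estimated correlation was 0.0643, although the medians of the arrays did not overlap (-0.25, -0.17 and 0.13 on Day 10, 0.46, 0.27 and 0.71 on Day 28), and medium and culture density stay open as untested.

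Asns, Chac1, Bcat1 and Atf4 were lower on Day 28 than on Day 2, and a candidate explanation is a lower response to amino acid shortage. Of 32 genes listed for it 26 were measured, with a median of -0.45 (camera p = 3.2e-07, p = 0.0701 with an estimated correlation), and 6 fell, among them Slc7a5 (-1.79), Psat1 (-1.70) and Psph (-1.20). Vegfa and Nupr1 had been seen before, and without them the median was -0.56. After quantile normalization 3 of the 4 genes passed and Atf4 did not (-0.73, adjusted p = 0.0513, against -0.79 before), which argues against scaling as the whole cause. No test separated a shortage of amino acids from other stresses. The endoplasmic reticulum list, which includes Asns, was also lower on Day 28 than on Day 2 (camera adjusted p = 0.0221, adjusted p = 0.0722 with an estimated correlation). Time in culture and the state of the medium are confounded with the days and stay open as untested.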
